A study of Oryza sativa with 6 samples.

How the data were processed

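The data are from 6 RNA-seq libraries of developing rice seeds at the filling stage, 3 of the near-isogenic line NIL-gaf1 (genotype labelled mutant) and 3 of NIL-GAF1 (labelled wild type). Groups were taken from the genotype and line labels. Per the labels' protocols, plants grew in a paddy field, total RNA was extracted with a column kit for plant tissue, and libraries were made by standard Illumina procedures. Bowtie version 0.12.2 is named in the submitters' processing notes. The counting tool, the genome build and the annotation are not given in the sources used here, nor is whether counting used strand, so overlapping and antisense genes are uncertain.

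The authors deposited 1 table for the whole series with 91080 features. Per the file headers it gives read counts per feature and FPKM (fragments scaled to transcript length and library total) for each library, with a gene identifier, a name that pairs a symbol with a locus identifier, a description and coordinates. The deposited counts are whole numbers without normalization. For all 18936 features with at least 10 counts in every library, the length implied by count and FPKM was equal across libraries within 0.1%, so for these the FPKM values add only that length. Other features were not checked. Counts were used for the main test. A description was given for 3813 features, a locus identifier for 29168 and a symbol for 1865. The 53250 features with EPlOSAG identifiers held at most 0.0854% of the counts of a library, and 53085 features had no counts in any library. Coordinates are those of the table. A separate reference table of gene names was not used for names or coordinates.

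Total counts ranged from 17236796 to 25402680 per library. A count of 0 allows at most 3 counts of the total. Library pairs within a line differed by far more than sampling noise (chi-square per gene 10.91 to 365.99), so no library was counted as a copy of another. Pearson correlations of log2 CPM across genes were 0.923 to 0.971 within the mutant, 0.954 to 0.964 within wild type and 0.803 to 0.906 between lines. The first principal component held 70.9% of the variance. TMM factors were 1.884, 1.571 and 1.157 for mutant libraries 1, 2 and 3 and 0.715, 0.627 and 0.652 for wild-type libraries 1, 2 and 3. The choice of scaling affects the direction of many genes, including some called with at least a 2-fold change.

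Mutant and wild type were compared with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit and glmQLFTest, line as the only term) on counts kept by filterByExpr (22937 features) with TMM normalization. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Standard errors of log2 fold changes were computed as the absolute log2 fold change divided by the square root of the F statistic. Normalized CPM are CPM of the TMM-scaled library size, and log2 CPM used a prior count of 2. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) and fry, with Benjamini-Hochberg adjustment over the 28 lists with at least 3 tested members. Values of single measures per library were compared by exact permutation (scipy 1.17.1). Windows of 50 consecutive tested genes were compared with 10000 random relabellings of the changed genes, one-sided. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

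The comparison, the tests, the gene lists and the rule for named genes were set before the data were examined. There were 15 lists given by locus (189 members) and 16 given by words in the description. Of the locus members 188 matched; PUL, a pullulanase, did not. For 11 members with several features at the locus the feature with the largest total was taken, except RAmy3B, taken by its description. The locus of the 10 kDa prolamin RP10 pairs with a feature of low counts, while another feature described as 10 kDa prolamin, OS03G0766100, is abundant and stands in the prolamin family. As set beforehand, features whose description contradicts their list were dropped: 4 microtubule proteins named SPIRAL1-like had matched the seed allergen words, which was noticed after list values had been seen. The peroxidase and transposon words matched no feature and the WRKY words matched 1 (log2 fold change 0.30, not called), so these 3 lists had no set test. Named genes were (a) among called genes with non-overlapping lines, a mean of at least 5 normalized CPM and a description that is not transposon, hypothetical, expressed or unknown, the 12 with the largest positive and the 12 with the largest negative log2 fold change, (b) up to 4 members of each list with the smallest adjusted p, called or not, and (c) AGPL2. These came to 125 genes, of which part are named in the text.

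Alternatives were the replicate number as a block, DESeq2 size factors in edgeR, no low-count filter, a mean of at least 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom, limma on log2(FPKM + 1) for features with a mean FPKM of at least 1, an adjusted p under 0.01, each library left out, an estimated correlation in camera, and windows of 20 and 100 genes. Total-count scaling, TMM computed without storage genes, total-count scaling with storage genes removed, and keeping the SPIRAL1-like features were chosen after seeing the data.

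The gene test was tested on simulated data for this comparison, with 22937 genes drawn from the means of the wild-type samples and 200 genes changed. It recovered 21% of 2-fold and 84% of 4-fold changes, with 117 calls of which 12 were false. Camera called 2 of 2 shifted sets and 0 of 50 unshifted sets. Genes were drawn independently of each other, so this does not test camera where the genes of a list are correlated. The window test was also tested on simulated data.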

Results

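RNA was profiled from developing rice (Oryza sativa) seeds at the filling stage, labelled 15 DAF, in a pair of near-isogenic lines grown in a paddy field. Near-isogenic lines share most of their genome and differ at a selected region. One line, NIL-gaf1, carries the genotype that the labels call mutant, and the other, NIL-GAF1, the genotype that they call wild type. Each line had 3 libraries. Total counts were 21200210, 24080348 and 25402680 in mutant libraries 1, 2 and 3, and 17236796, 19704794 and 22454000 in wild-type libraries 1, 2 and 3. A count of 0 allows a level of up to 0.0753 to 0.102 in the mutant and 0.205 to 0.244 in the wild-type libraries, in normalized CPM (counts scaled to a common library total). This limit is taken as 3 counts per library and covers counting error only. The labels do not say whether libraries of a line came from separate plants, so p-values measure the spread between these samples, which may be technical. The single comparison was mutant against wild type, and it asks how the transcripts of filling grains differ between the lines. Levels are given as normalized CPM, mean ± SD over n = 3 libraries per line, and a positive log2 fold change is a higher level in the mutant line.

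Transcripts of seed storage proteins made up far less of the mutant libraries. The 14 genes of the storage protein list (glutelins, prolamins, a globulin and the seed allergen RAG2) took 39.8% ± 2.54 (SD, n = 3) of all counts in wild type and 9.73% ± 10.7 (SD, n = 3) in the mutant. The shares were 0.413%, 7.29% and 21.5% in mutant libraries 1, 2 and 3, against 37.3%, 42.4% and 39.6% in wild-type libraries 1, 2 and 3. Without mutant library 3 the mutant mean was 3.85%. All 3 mutant libraries lay below all 3 wild-type libraries, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows. More features were detected in the mutant, 32109 to 33566 against 29358 to 29679 (exact permutation p = 0.1, two-sided). A feature was detected if it had any count, so this depends on depth. In all, 25 storage and seed allergen genes took 42.2% to 48.3% of wild-type counts and 0.453% to 22.8% of mutant counts. That left a smaller share for other features in wild type, and detection was not compared at equal depth.

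**Figure D1:**
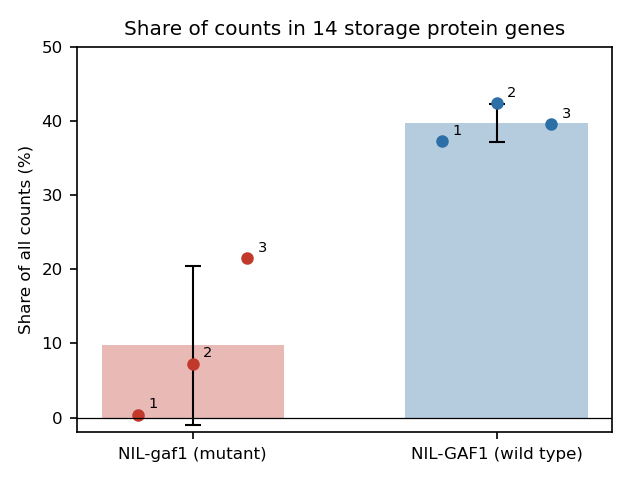
Share of all counts (%, vertical axis) held by the 14 storage protein genes in the mutant and wild-type lines; points are libraries with their replicate numbers, bars are means and error bars are SD (n = 3). The mutant libraries spread from 0.413% to 21.5%, all below the wild-type libraries at 37.3% to 42.4%.

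The titles carry the symbol gif2, a name also used for AGPL2, a large subunit of ADP-glucose pyrophosphorylase, which makes the sugar nucleotide used for starch. Whether AGPL2 is the locus that differs between these lines is not given by the labels. AGPL2 (OS01G0633100, chromosome 1, 25353805 to 25361883, genome build not given in the sources used here) was at 1102, 1811 and 2486 normalized CPM in mutant libraries 1, 2 and 3 and at 2868, 2954 and 3176 in wild-type libraries 1, 2 and 3. The log2 fold change of -0.74 (SE 0.41) did not pass the test (edgeR adjusted p = 0.21), and it was 0.38 with total-count scaling.

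Of 22937 genes tested, 7148 changed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 3619 higher and 3529 lower in the mutant. Of these, 4321 differed at least 2-fold, 2235 higher and 2086 lower. In 11250 of all tested genes (49%) the 3 mutant libraries did not overlap the 3 wild-type libraries, which chance gives for 10% of genes. The balance of higher and lower calls depended on the scaling. It was 3619 to 3529 (50.6% higher) with TMM normalization, 16481 to 863 (95% higher) with total-count scaling, 14576 to 868 (94.4% higher) with limma on log2(FPKM + 1), and 8369 to 1816 (82.2% higher) with total-count scaling after 25 storage and seed allergen genes were removed. The median log2 fold change of all tested genes was 0.06 with TMM and 1.27 with total-count scaling, so each direction given here is relative to the typical gene. Of 4929 genes called under both TMM and total-count scaling, 458 had opposite signs. Leaving out mutant library 2 left 4012 calls, and leaving out wild-type library 1 left 4557.

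Among the 12 largest rises of described genes was SUS3, a sucrose synthase that cleaves sucrose for use in the seed (OS07G0616800, chromosome 7, 25429639 to 25435132). It was at 1716 ± 75.4 normalized CPM in the mutant and 106 ± 42.8 in wild type, 16.3-fold higher (log2 fold change 4.02, SE 0.38, edgeR adjusted p = 4.2e-04). Germin-like protein 9-3 (OS09G0568700, chromosome 9, 22699925 to 22700959) was at 32.3 ± 8.03 in the mutant, and in wild type it had no counts in libraries 1 and 2 and 7 counts, or 0.479 normalized CPM, in library 3 (log2 fold change 7.48, SE 0.62, adjusted p = 2.8e-04). Without wild-type library 3 no wild-type counts are left, and against 3 counts per library it was at least 132-fold higher. The other rises selected by size were Fimbrin-2, an actin-bundling protein (log2 fold change 4.56), the peroxidase PRX112 (4.34), a microtubule-associated protein of the RP/EB family (4.07), the expansin EXPB11 (4.01), the response regulator RR33 (3.86), Scarecrow-like protein 28 (3.84), Germin-like protein 8-12 (3.66), the ethylene-forming enzyme ACO1 (3.40), AGO14 (3.38) and the transcription factor PCF6 (3.35). Single libraries moved some of these values. Without mutant library 1 the log2 fold change was 3.84 for Fimbrin-2, 3.66 for PRX112, 3.28 for EXPB11 and 2.61 for Germin-like protein 8-12. Without wild-type library 2 it was 5.13 for PRX112, 5.86 for EXPB11 and 4.54 for RR33. EXPB11 did not pass without wild-type library 1 (adjusted p = 0.067) or 3 (0.053).

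The largest falls included seed allergen genes on chromosome 7. RAG1 (OS07G0214100, chromosome 7, 6254882 to 6255558) was at 1.58, 33.2 and 147 normalized CPM in mutant libraries 1, 2 and 3 and at 4752, 3523 and 6096 in wild-type libraries 1, 2 and 3, 78.9-fold lower (log2 fold change -6.30, SE 1.42, adjusted p = 0.013). RA16, an alpha-amylase/trypsin inhibitor at 6276107 to 6276753 of chromosome 7, fell by 5.25 on the log2 scale (SE 1.05, adjusted p = 0.008), and RAG2, at 6258917 to 6259662, fell by 5.34 (SE 1.26, adjusted p = 0.015). CYCP2-1, a P-type cyclin (OS04G0552300, chromosome 4, 27661549 to 27662832), was at 0.206 ± 0.0923 against 18.3 ± 5.89, 90-fold lower (log2 fold change -6.49, SE 0.39, adjusted p = 1.3e-04). A probable purple acid phosphatase 20 (OS12G0151000, chromosome 12, 2535927 to 2538830) was at 2.06 ± 0.517 against 173 ± 48.6, 84.1-fold lower (log2 fold change -6.39, SE 0.32, adjusted p = 9.8e-05). The other falls selected by size were a CCCH zinc finger protein (log2 fold change -5.70), Germin-like protein 3-8 (-5.52), Germin-like protein 3-3 (-5.27), a putative UPF0496 protein (-4.99), the prolamin PROLM7 (-4.95), a 17 kDa alpha-amylase/trypsin inhibitor (-4.42) and protein phosphatase 2C 27 (-4.25). Without mutant library 3 the log2 fold change was -8.12 for RAG1 (279-fold), -7.05 for RAG2, -6.74 for RA16, -7.30 for PROLM7, -6.36 for the 17 kDa inhibitor, -6.33 for the zinc finger protein and -5.30 for the phosphatase 2C. It was -4.33 for PROLM7 without mutant library 1 and -4.52 for Germin-like protein 3-3 without wild-type library 3. Without mutant library 2, RAG1 (adjusted p = 0.059), RAG2 (0.076) and the 17 kDa inhibitor (0.12) did not pass. The last did not pass without wild-type library 1, 2 or 3 either (0.071 to 0.077).

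**Figure D2:**
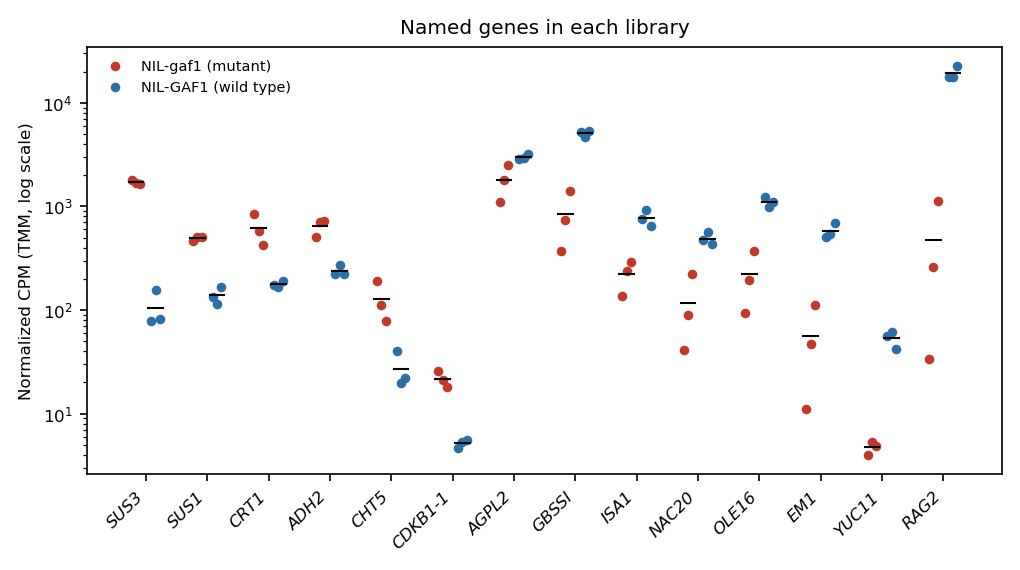
Normalized CPM (TMM, log axis) of 14 named genes (horizontal axis) in each library; red points are mutant libraries, blue points wild-type libraries, black lines group means (n = 3). SUS3 sits at 1659 to 1802 in the mutant and 79.2 to 155 in wild type, while RAG2 spans 33.9 to 1132 in the mutant and 17619 to 22418 in wild type.

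As a group, storage protein transcripts were lower in the mutant, with a wide spread between mutant libraries. The median log2 fold change of the 14 genes was -2.89, and camera called the list lower (adjusted p = 0.0019, and adjusted p = 0.63 with an estimated correlation). Gene by gene, 2 of the 14 fell (RAG2 and the 16 kDa prolamin RP16) and 12 did not pass, and 1 fell when adjusted over the list alone. GluA1, a major glutelin, was at 332, 8585 and 28897 normalized CPM in mutant libraries 1, 2 and 3 and at 109922 ± 6768 in wild type (log2 fold change -3.12, SE 1.57, adjusted p = 0.16). GluC was at 2898 ± 3403 against 53730 ± 5276 (log2 fold change -4.21, adjusted p = 0.054). The keyword families gave the same direction. They are not separate evidence throughout, as all 8 glutelins, and RAG2 of the seed allergens, are also in the storage protein list. All 8 glutelin genes were negative (median -2.72, none called, camera adjusted p = 0.021), as were all 5 tested prolamin genes (median -3.63, 1 called over all genes and 5 over the list alone, camera adjusted p = 0.021). All 5 seed allergen genes fell (5 over all genes and 5 adjusted over the list alone, median -5.25, camera adjusted p = 0.0028). Each of these 3 camera calls was lost with an estimated correlation (adjusted p = 0.63 for each). With mutant libraries 1, 2 and 3 and then wild-type libraries 1, 2 and 3 left out in turn, 8, 0, 7, 1, 1 and 1 genes of the storage protein list were called lower. In the same order these were 3, 0, 2, 0, 0 and 0 glutelins, 5, 1, 5, 1, 1 and 1 prolamins, and 5, 1, 5, 3, 3 and 3 seed allergens. The medians without mutant library 3 were -4.61 for the storage list, -4.53 for glutelins, -6.02 for prolamins and -6.74 for seed allergens. RP16 did not pass without mutant library 2 (adjusted p = 0.14) or wild-type library 1, 2 or 3 (0.087 to 0.09). GluC and GluA1 passed without mutant library 1 (adjusted p = 0.0083 and 0.043), as did GluC without mutant library 3 (log2 fold change -5.77, adjusted p = 0.021). Some members of these families may be alike enough in sequence for reads to be split between them, which was not measured, so values of single members are uncertain.

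Transcripts of most embryo and aleurone markers, taken here to stand for seed tissues other than the starchy endosperm, fell as well. Of 9 members, 7 fell and 2 did not pass, with 8 lower when adjusted over the list alone (median log2 fold change -3.14, camera adjusted p = 0.0019, and adjusted p = 0.63 with an estimated correlation). EM1, an embryonic abundant protein, was at 56.2 ± 50.5 normalized CPM in the mutant and 582 ± 101 in wild type, 10.3-fold lower (log2 fold change -3.37, SE 0.72, adjusted p = 0.01). OLE16, an oil-body oleosin, was at 221 ± 142 against 1103 ± 116, 4.99-fold lower (log2 fold change -2.32, SE 0.48, adjusted p = 0.0088). The dehydrins RAB16C and RAB16D fell by 3.33 and 3.89 on the log2 scale. The 2 that did not pass were LEA3 (log2 fold change -1.59, edgeR adjusted p = 0.066) and OSH1 (0.12, adjusted p = 0.72). Of the 7 genes described as oleosins, dehydrins or late embryogenesis proteins, which overlap this list, 6 fell (7 adjusted over the list alone, camera adjusted p = 0.0019, and adjusted p = 0.63 with an estimated correlation). Leaving out mutant libraries 1, 2 and 3 and then wild-type libraries 1, 2 and 3 gave 8, 4, 8, 4, 5 and 4 falls among the embryo and aleurone markers and 7, 3, 7, 3, 3 and 3 in the overlapping family. Without mutant library 3 the medians were -4.29 and -2.95, and the falls were 20.4-fold for EM1, 7.74-fold for OLE16, 19.5-fold for RAB16C and 23.7-fold for RAB16D. For green pericarp markers none of 19 passed over all genes or adjusted over the list alone, and the median was 0.04 (camera adjusted p = 0.85). With total-count scaling 16 of the 19 were called higher and none lower (median 1.31), close to the shift of all genes. Without mutant library 1, 3 were called lower, and without mutant library 3, 2 were called higher. None of the 6 chlorophyll-binding genes passed either (median 0.20, camera adjusted p = 0.74), and 1 was called lower without mutant library 1.

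Of 15 regulators of endosperm gene expression, 5 fell relative to the typical gene and 10 did not pass, with the same counts adjusted over the list alone (median -1.16, camera adjusted p = 0.036, and adjusted p = 0.63 with an estimated correlation). Total-count scaling, which moves all genes up, gave 5 higher and 1 lower with a median of 0.00. The falls numbered 7, 2, 9, 2, 2 and 2 without mutant libraries 1, 2 and 3 and then wild-type libraries 1, 2 and 3 in turn, with 1 rise without mutant library 1. NAC20, a transcription factor acting on storage genes, was at 118 ± 94.4 against 489 ± 64.6, 4.15-fold lower (log2 fold change -2.05, SE 0.54, adjusted p = 0.024). RPBF, the prolamin box binding factor, was 3.55-fold lower (SE 0.55 on the log2 scale, adjusted p = 0.038) and NAC129 was 2.76-fold lower (SE 0.28, adjusted p = 0.0066). NF-YB1 was 2.24-fold lower (log2 fold change -1.16, SE 0.18, adjusted p = 0.003), and its log2 fold change was 0.00 with total-count scaling. NAC20 and RPBF did not pass without mutant library 2 (adjusted p = 0.093 and 0.13) or without wild-type library 1 (0.065 and 0.095), 2 (0.068 and 0.1) or 3 (0.056 and 0.077). Without mutant library 3 they were 7.61-fold and 6.67-fold lower.

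The starch synthesis genes went both ways. Of 31 tested, 4 rose, 6 fell and 21 did not pass, with the same counts adjusted over the list alone, and the median was -0.16 (1.13 with total-count scaling, camera adjusted p = 0.23). These counts moved with single libraries: without mutant libraries 1, 2 and 3 and then wild-type libraries 1, 2 and 3 in turn, 2, 0, 4, 0, 1 and 0 were called higher and 6, 1, 11, 3, 3 and 4 lower. GBSSI, the granule-bound starch synthase that makes amylose (OS06G0133000, chromosome 6, 1765622 to 1770574), was at 847 ± 532 against 5071 ± 375, 5.99-fold lower (log2 fold change -2.58, SE 0.56, adjusted p = 0.011). The debranching enzyme ISA1 was at 222 ± 78.5 against 771 ± 133, 3.47-fold lower (SE 0.32 on the log2 scale, adjusted p = 0.0053). AGPS1, a small subunit of ADP-glucose pyrophosphorylase, was 1.84-fold higher (SE 0.24 on the log2 scale, adjusted p = 0.025). The starch synthase SSIIc was 1.77-fold lower (adjusted p = 0.01), with a log2 fold change of 0.34 under total-count scaling. Without mutant library 2, GBSSI (adjusted p = 0.063), SSIIc (0.05) and AGPS1 (0.092) did not pass, nor did AGPS1 without wild-type library 1 (0.11) or 3 (0.1). GBSSI was 9.23-fold lower without mutant library 3.

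Among the 16 tested genes of sucrose supply, 3 rose, 1 fell and 12 did not pass, with the same counts adjusted over the list alone. In turn without mutant libraries 1, 2 and 3 and then wild-type libraries 1, 2 and 3, 4, 2, 4, 2, 3 and 2 were called higher and 2, 0, 1, 1, 1 and 1 lower. The members that moved were sucrose synthases and a sugar transporter. Besides SUS3, SUS1 was at 494 ± 22.6 against 138 ± 27.1, 3.57-fold higher (SE 0.22 on the log2 scale, adjusted p = 0.001), and SWEET15 was 1.52-fold higher (adjusted p = 0.021). SUS4 was at 539 ± 252 against 2062 ± 227, 3.83-fold lower (SE 0.42 on the log2 scale, adjusted p = 0.011). SUS4 and SWEET15 did not pass without mutant library 2 (adjusted p = 0.056 and 0.088), nor SWEET15 without wild-type library 1 (0.099) or 3 (0.093). The list as a whole was not called (camera adjusted p = 0.55, direction up), and its median of -0.05 and mean of 0.17 differed in sign. No member of the alpha-amylase list passed among 3 tested, none when adjusted over the list alone (median -0.92, and 0.30 with total-count scaling, camera adjusted p = 0.36), with 1 lower without mutant library 1 and 2 lower without mutant library 3. Its median was -0.12 without wild-type library 3.

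All 10 genes of diterpenoid phytoalexin synthesis, antimicrobial compounds of rice, were positive, and 6 of them rose (7 adjusted over the list alone, none fell, median 1.43). That number was 3, 2, 8, 4, 3 and 1 without mutant libraries 1, 2 and 3 and then wild-type libraries 1, 2 and 3 in turn. Camera called this list higher (adjusted p = 0.012, adjusted p = 0.63 with an estimated correlation, 0.13 with total-count scaling, and 7.7e-04 to 0.029 with each library left out). KSL4, a syn-pimaradiene synthase of that pathway, was at 18.8 ± 6.21 against 5.95 ± 1.84, 3.17-fold higher (SE 0.32 on the log2 scale, adjusted p = 0.0064), and CYP76M8 was 6.82-fold higher (adjusted p = 0.028). CYP76M8 was 3.22-fold higher without mutant library 1, and it did not pass without wild-type library 1 (adjusted p = 0.052), 2 (0.089) or 3 (0.094). In the chitinase family 3 of 7 rose (3 adjusted over the list alone, camera adjusted p = 0.09), led by CHT5 at 128 ± 57.8 against 27.2 ± 11.1, 4.70-fold higher (SE 0.39 on the log2 scale, adjusted p = 0.0045). Among defence genes 2 of 10 rose, PR1a (2.81-fold) and WRKY45 (2.40-fold), 2 when adjusted over the list alone (camera adjusted p = 0.1). In the low-oxygen list 3 of 6 rose, and 3 when adjusted over the list alone (camera adjusted p = 0.088). ADH2, an alcohol dehydrogenase, was 2.68-fold higher (SE 0.24 on the log2 scale, adjusted p = 0.0039), PDC1 3.36-fold and AOX1A 3.94-fold. In the lipid transfer family 4 of 7 rose, and 4 when adjusted over the list alone (camera adjusted p = 0.062), with LTP2-A at 114 ± 20.6 against 25.5 ± 10.1. Heat shock genes gave 3 rises among 15 (3 adjusted over the list alone, HSP70b 2.82-fold higher, adjusted p = 0.0032), while their median was -0.47 (0.74 with total-count scaling, camera adjusted p = 0.55). The small heat shock family gave 1 rise and 1 fall among 10, the same adjusted over the list alone (camera adjusted p = 0.2). In the same order of left-out libraries, the rises numbered 3, 3, 3, 3, 3 and 4 for chitinases, 1, 2, 3, 1, 4 and 1 for defence, 3, 2, 3, 2, 3 and 2 for low oxygen and 3, 3, 4, 2, 4 and 2 for lipid transfer. They were 3, 1, 3, 2, 1 and 1 for heat shock and 1, 0, 1, 0, 0 and 0 for small heat shock genes. Falls numbered 0, 0, 2, 0, 0 and 0 for heat shock and 1, 1, 4, 1, 1 and 1 for small heat shock genes. WRKY45 did not pass without mutant library 1 (adjusted p = 0.068) or wild-type library 1 (0.11) or 3 (0.1), and AOX1A without mutant library 2 (0.062) or wild-type library 1 (0.056) or 3 (0.057).

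Compared after their values were seen, the medians of 3 defence-related lists went down from mutant library 1 to 3, as did those of green pericarp markers. Relative to the wild-type mean, the list medians in mutant libraries 1, 2 and 3 were 1.85, 1.61 and 0.72 for diterpenoid phytoalexins, 1.35, 0.76 and 0.29 for defence and 1.63, 0.69 and 0.18 for chitinases. They were 0.50, -0.05 and -0.39 for green pericarp markers. Wild-type libraries 1, 2 and 3 had medians of 0.51, 0.31 and -0.74 for diterpenoid phytoalexins and -0.04, 0.48 and -0.32 for defence. Their medians were 0.27, -0.40 and -0.15 for chitinases and 0.27, -0.16 and -0.07 for green pericarp markers. For defence and chitinases mutant library 3 thus lay within the range of the wild-type libraries.

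The list for folding in the endoplasmic reticulum, where storage proteins fold, gave 3 rises among 13 tested and no fall, with the same counts adjusted over the list alone (median 0.48, camera adjusted p = 0.09). With each library left out the adjusted p ran from 0.0075, without mutant library 1 (5 higher, 0 lower), to 0.27, without mutant library 3 (3 higher, 2 lower). Between 3 and 4 were higher and 0 lower without any other library. CRT1, a calreticulin, was at 618 ± 211 against 177 ± 11.4, 3.49-fold higher (log2 fold change 1.80, SE 0.29, adjusted p = 0.0032), CRT2 was 4.12-fold higher and BiP4 4.52-fold higher. These 3 are chaperones, while the list also holds the stress sensor IRE1, the transcription factor bZIP50 and the oxidase ERO1, which did not pass. The main luminal chaperone BiP1, named here after its values were seen, was at 488, 1138 and 1939 in mutant libraries 1, 2 and 3 and at 581 to 683 in wild type, and did not pass (adjusted p = 0.18, and 0.011 without mutant library 1).

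In the family described by the word cyclin, which also holds cyclin-dependent kinases and their inhibitors, 9 of 40 rose and 11 fell (9 and 14 adjusted over the list alone, median -0.24, camera adjusted p = 0.55). With total-count scaling the median was 1.01, with 28 higher and 1 lower. Named here after their values were seen, the falls included EL2 and KRP6, inhibitors of cyclin-dependent kinases, and CYCT1-1 (OS02G0133000), known for a role in transcription. The mitotic kinases CDKB1-1 and CDKB2-1 were 4.18-fold and 5.41-fold higher (SE 0.18 and 0.30 on the log2 scale, adjusted p = 3.7e-04 and 0.0011), while the kinase inhibitor SMR1 was 2.08-fold lower (adjusted p = 0.0032, log2 fold change 0.16 with total-count scaling). In the histone family 9 of 22 rose and 4 fell (10 and 4 adjusted over the list alone, median 0.33, camera adjusted p = 0.055), with a probable histone H2A.5 at 58.3 ± 8.84 against 13.4 ± 1.9 (4.34-fold higher, adjusted p = 2.7e-04). Successively without mutant libraries 1, 2 and 3 and then wild-type libraries 1, 2 and 3, the cyclin family had 9, 8, 10, 8, 9 and 8 rises and 8, 7, 13, 8, 8 and 8 falls. The histone family had 9, 8, 8, 8, 8 and 8 rises and 3, 0, 5, 2, 2 and 4 falls.

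In the auxin and cytokinin list 2 of 5 tested genes fell and none rose, with the same counts adjusted over the list alone. Both were auxin synthesis genes of the YUCCA family. YUC11 (OS12G0189500, chromosome 12, 4515673 to 4517450) was at 4.74 ± 0.69 against 53.2 ± 10.3, 11.2-fold lower (log2 fold change -3.49, SE 0.20, adjusted p = 1.3e-04), and YUC9 was 6.08-fold lower (SE 0.42 on the log2 scale, adjusted p = 0.0034). The list was called lower by camera (adjusted p = 0.021, adjusted p = 0.63 with an estimated correlation, and 0.017 to 0.093 with each library left out, the highest without mutant library 3), with a median of -0.12 that was 0.96 under total-count scaling. Without wild-type libraries 1, 2 and 3 in turn, when 6 members were tested, its median was 0.08, 0.13 and 0.10. In nitrogen metabolism 1 of 6 rose and 3 fell (2 and 4 adjusted over the list alone, median -0.95, and 0.20 with total-count scaling, camera adjusted p = 0.34). The glutamine synthetase gene GS1;2 was 2.36-fold higher (SE 0.21 on the log2 scale, adjusted p = 0.0043) and its paralog GS1;3 was 4.62-fold lower (SE 0.40, adjusted p = 0.0056). In abscisic acid metabolism 2 of 6 rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.55), with NCED5 3.54-fold higher and NCED1 3.29-fold lower (adjusted p = 0.0015 and 0.043). The proteasome family gave 5 rises and 1 fall among 18, the same adjusted over the list alone (camera adjusted p = 0.37), and 18 higher and 0 lower with total-count scaling. Ribosomal protein genes gave 3 rises among 58 (2 adjusted over the list alone, camera adjusted p = 0.34), and 57 higher and 0 lower with total-count scaling (median 1.33, against 0.15 with TMM). F-box genes gave 3 rises and 3 falls among 22 (4 and 6 adjusted over the list alone, camera adjusted p = 0.55), and the median was -0.22, against 1 with total-count scaling. Taking out mutant libraries 1, 2 and 3 and then wild-type libraries 1, 2 and 3 in turn gave 1, 1, 2, 1, 1 and 1 rises and 3, 1, 3, 2, 2 and 2 falls in nitrogen metabolism. In that order abscisic acid metabolism had 1, 1, 1, 1, 2 and 1 rises and 0, 0, 1, 0, 1 and 0 falls. The proteasome family had 5, 3, 3, 3, 4 and 3 rises and 0, 0, 1, 0, 0 and 0 falls. F-box genes had 3, 2, 2, 2, 2 and 2 rises and 3, 2, 4, 2, 2 and 3 falls. Ribosomal protein genes had 4, 2, 8, 2, 3 and 2 rises and no fall. The auxin and cytokinin list had 2 falls each time, with 1 rise without mutant library 3. NCED1 did not pass without mutant library 1 (adjusted p = 0.059) or 2 (0.088) or wild-type library 1 (0.16) or 3 (0.097).

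**Figure D3:**
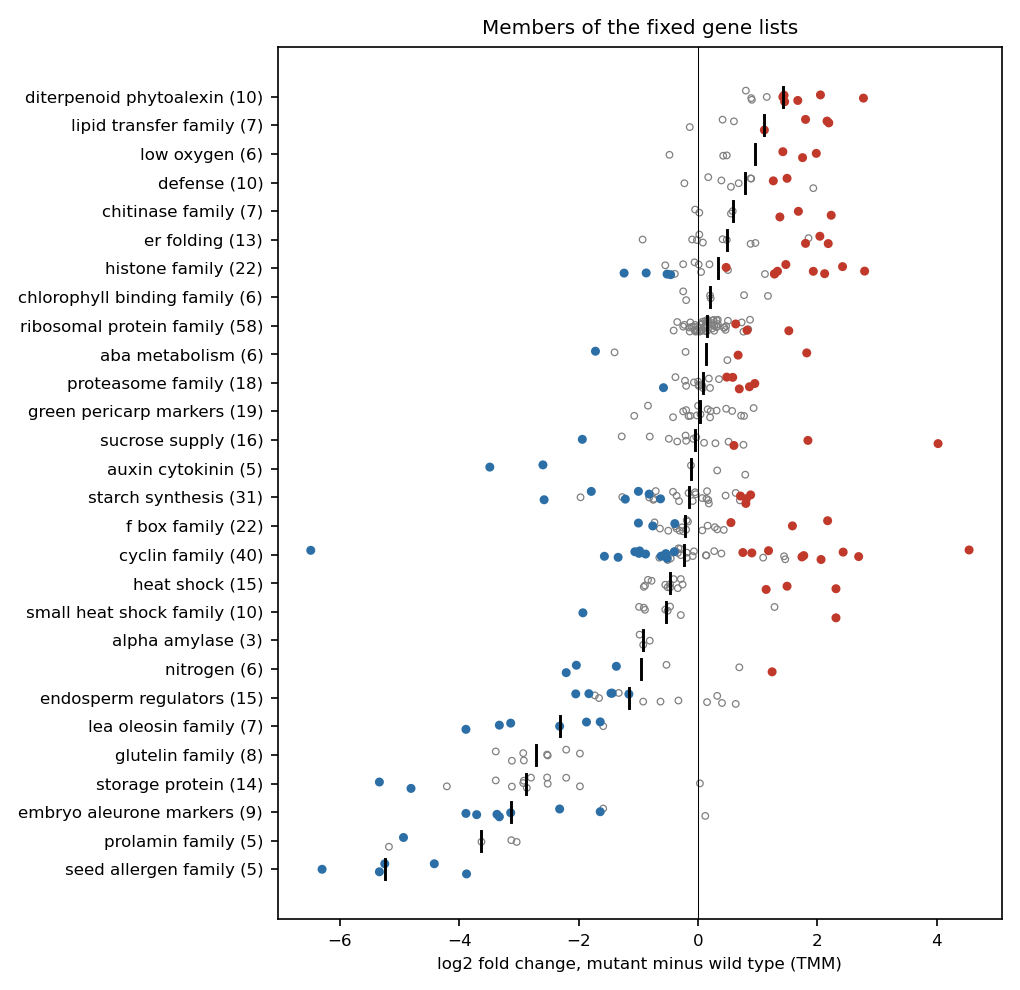
Log2 fold change (mutant minus wild type, TMM) of each tested member of the 28 fixed gene lists with at least 3 tested members, the number tested in brackets; filled points passed the test over all genes (red higher, blue lower in the mutant), open points did not, and black ticks are list medians. Medians run from -5.25 in the seed allergen family to 1.43 in the diterpenoid phytoalexin list; with total-count scaling the median of all genes moves from 0.06 to 1.27.

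By camera with a preset correlation of 0.01, 9 of the 28 tested lists were called, 8 lower and 1 higher, and none of the 9 calls held with an estimated correlation. Some of the 8 lower lists share genes, while the prolamin family, the endosperm regulators and the auxin and cytokinin list share no tested gene with the others. The glutelin family lies within the storage protein list, and the oleosin and dehydrin family overlaps the embryo and aleurone list. By fry, which tests whether the genes of a list move on balance one way, the auxin and cytokinin list, the seed allergen family and the F-box family (adjusted p = 0.017 for each), the embryo and aleurone list (0.022), the starch list and the oleosin and dehydrin family (0.036 for each) and the prolamin family (0.037) were lower. The low-oxygen, histone and lipid transfer lists (fry adjusted p = 0.015 for each) and the folding list (0.036) were higher. Fry was run with TMM only. It does not compare a list with the other genes, so its directions depend on that scaling. With total-count scaling the median was 1.13 for starch, 1 for F-box genes and 0.96 for the auxin and cytokinin list. The medians of the other lists that fry called lower stayed negative. Of the 9 lists called by camera, fry did not call storage proteins (adjusted p = 0.057), glutelins (0.077), endosperm regulators (0.091) or diterpenoid phytoalexins (0.091).

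With total-count scaling, which moves all genes up in the mutant, the counts of members called higher and lower were 20 and 2 for starch synthesis, 9 and 1 for sucrose supply, 12 and 0 for folding, 19 and 0 for histones and 17 and 0 for F-box genes. They were 10 and 0 for diterpenoid phytoalexins, 9 and 0 for defence, 5 and 0 for chitinases, 5 and 0 for low oxygen, 7 and 0 for lipid transfer, 9 and 0 for heat shock and 5 and 1 for small heat shock genes. Abscisic acid metabolism had 3 and 0, the auxin and cytokinin list 3 and 2, nitrogen metabolism 2 and 2, the alpha-amylase list 0 and 0 and chlorophyll-binding genes 6 and 0. The storage protein list had 1 and 3, glutelins 0 and 0, prolamins 0 and 4, seed allergens 0 and 5, embryo and aleurone markers 1 and 6, and the oleosin and dehydrin family 0 and 4.

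Changed genes of both directions pooled did not pass the window test. The fullest window of 50 consecutive tested genes, on chromosome 8 from 21555138 to 22550675, held 28 changed genes against 15.6 per window on average (one-sided permutation p = 0.59 over 10000 relabellings). Windows of 20 and 100 genes gave p = 0.46 and p = 0.89 by the same permutation. Genes lower in the mutant, tested alone after the data were seen, filled a window of chromosome 7 with 23 against 7.7 on average (permutation p = 0.0015, adjusted p = 0.0067). That result did not pass with some single libraries left out. The window held 24, 7, 25, 13, 14 and 15 such genes without mutant libraries 1, 2 and 3 and then wild-type libraries 1, 2 and 3. In that order the average per window was 7, 4.3, 9.2, 5, 5.8 and 5.3, as the number of genes called lower changed too. The fullest window of the genome then had a permutation p of 0.0001, 0.17, 0.0014, 0.24, 0.3 and 0.37.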

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

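Of the settings here, total-count scaling, TMM without storage genes, total-count scaling with storage genes removed, and the SPIRAL1-like features kept were chosen after the data were seen. Between 5543 and 7925 genes changed with the replicate block (6048), DESeq2 size factors in edgeR, no low-count filter, a mean of at least 5 CPM, the DESeq2 Wald test and limma-voom, against 7148 in the reported test. An adjusted p under 0.01 gave 3364 (1605 higher, 1759 lower, 2657 at least 2-fold), by construction of the threshold. A mean of at least 5 CPM left 2634 genes at least 2-fold, with fewer genes tested. Limma on log2(FPKM + 1) gave 15444 (14576 higher, 868 lower, 9808 at least 2-fold), total-count scaling 17344 (16481 higher, 863 lower, 14666 at least 2-fold) and total-count scaling with storage genes removed 8369 higher, 1816 lower and 6498 at least 2-fold; these settings move the zero point of all genes. With each library left out, 4012 to 8328 genes changed, 2003 to 4040 higher and 2009 to 4288 lower, and 3116 to 5314 at least 2-fold; the lowest values came without mutant library 2 and the highest without mutant library 3. Libraries with the same number did not deviate together (r = 0.068, -0.043 and -0.025 across genes, and only libraries numbered 1 correlated best with each other), so the numbers do not pair the samples; the replicate block gave 6048 calls, 3001 higher and 3047 lower, and added calls of the chitinase (0.018) and lipid transfer (0.028) lists.

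Gene lists called numbered 9 in the reported test, 8 to 12 with each library left out and 0 with an estimated correlation, where each of the 9 lists had an adjusted p of 0.63; the cause was not tested for these lists. Adjusted p ranges with each library left out were 0.017 to 0.093 for the auxin and cytokinin list, 0.012 to 0.14 for chitinases, 0.046 to 0.22 for defence, 0.0075 to 0.27 for folding in the endoplasmic reticulum, 0.027 to 0.093 for histones, 0.024 to 0.093 for lipid transfer, 0.027 to 0.15 for low oxygen, 0.32 to 0.99 for green pericarp and 0.56 to 0.85 for chlorophyll binding; the green pericarp and chlorophyll lists, not called in any of these, changed direction without mutant library 1 and the former also without wild-type library 2 or 3. With total-count scaling the diterpenoid list was no longer called (0.13), the folding (0.047), histone (0.0068), proteasome (0.0033) and ribosomal (0.0027) lists were called higher, and the abscisic acid (0.98), F-box (0.65) and green pericarp (0.93) lists changed direction, uncalled. With the SPIRAL1-like features kept the seed allergen list had an adjusted p of 0.11.

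Of the 125 genes selected by the rule, all kept direction and call with DESeq2 size factors and with TMM without storage genes, and none changed direction with the replicate block, no low-count filter, DESeq2 or limma-voom. Calls were lost in 5 genes with the replicate block, 11 with no low-count filter, 8 with limma-voom, 4 with limma on log2(FPKM + 1), 4 with total-count scaling, 5 with storage genes removed and 33 at an adjusted p under 0.01. Without mutant libraries 1, 2 and 3, 6, 26 and 2 calls were lost, and without wild-type libraries 1, 2 and 3, 21, 12 and 23. Calls were gained in 6 genes with the replicate block, 18 with DESeq2, 6 with limma-voom, 19 with limma on log2(FPKM + 1), 17 with total-count scaling and 8 with storage genes removed, and in 12, 0, 13, 0, 1 and 0 without mutant libraries 1, 2 and 3 and then wild-type libraries 1, 2 and 3. Log2 fold changes that changed sign were, with total-count scaling, SSIIc 0.34, ERdj3B 0.15, NF-YB1 0.00, RAmy2A 0.11, RAmy3E 0.30, RAmy3D 0.39, LHCA3 0.19, RBCS2 0.40, HSP17h 0.27, LHCA4 1.04, HSP17.9A 0.12, SMR1 0.16, PAG1 0.60, LOC_Os10g24900 0.17, TULP1 0.43 and AGPL2 0.38. With limma on log2(FPKM + 1) they were SSIIc 0.31, ERdj3B 0.08, RAmy2A 0.05, RAmy3E 0.23, RBCS2 0.22, HSP17h 0.30, LHCA4 0.86, HSP17.9A 0.08, SMR1 0.12, PAG1 0.58, LOC_Os10g24900 0.16, TULP1 0.38 and AGPL2 0.37, and with storage genes removed LHCA4 0.28.
With each library left out, sign changes occurred in RAmy3D -1.47 to 0.63, TAR_FIB -0.14 to 0.65, LHCB1 -0.12 to 0.33 and CHT6 -0.01 to 0.90, none called in the reported test. The cause was not tested beyond the scaling. A count of 0 allows up to 0.0753 to 0.244 normalized CPM, the limit that depth sets on absence. Recovery of simulated changes was 84% for 4-fold and 21% for 2-fold and was not split by count.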

Other observations

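Every test in this part was chosen after the results were seen. Some genes moved far in the mutant while its 3 libraries stayed close together. Of 312 changed genes at least 8-fold apart with a mean of at least 5 normalized CPM, 32 (10.3%) had mutant libraries within 0.5 on the log2 scale, 17 higher and 15 lower. Selected after their values were seen, they include SUS3 (1802, 1687 and 1659 in mutant libraries 1, 2 and 3), YUC11 (3.99, 5.35 and 4.87), Scarecrow-like protein 28 (13.9, 12.1 and 10.4) and LOC_Os03g05334, a gene with no description (108, 92.1 and 83.2, against 1.79, 3.48 and 2.53 in wild-type libraries 1, 2 and 3). The storage protein list had medians of -8.04, -3.66 and -1.62 (log2, relative to the wild-type mean) in mutant libraries 1, 2 and 3.

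Genes lower in the mutant gathered on chromosome 7 when all libraries were used. The fullest window of 50 tested genes ran from 6134016 to 7232294 and held 23 of them against 7.7 on average (one-sided permutation p = 0.0015, adjusted p = 0.0067 over the 9 window tests run on changed, higher and lower genes). It includes 5 genes of the storage and seed allergen lists, between 6254882 and 6433104. The relabelling takes neighbouring genes as independent. The p-values therefore do not allow for neighbours of 1 family that fall together. The windows of 20 and 100 genes overlap it, with 15 and 34 such genes (permutation p = 0.0001, the smallest that the relabellings can give, and 0.0077). With 1 library left out, the window of 50 held 24 without mutant library 1 and 25 without mutant library 3 (permutation p = 0.0001 and 0.0014). It held 7 without mutant library 2 and 13, 14 and 15 without wild-type libraries 1, 2 and 3. There the fullest window of the genome did not pass (permutation p = 0.17, 0.24, 0.3 and 0.37). The averages per window, in the order of these settings, were 7, 9.2, 4.3, 5, 5.8 and 5.3. They moved with the number of genes called lower, which ran from 1967 to 4208.

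The mutant libraries were spread along the direction that separates the lines. Across 22937 genes, mutant library 3 minus library 1 correlated with wild type minus mutant library 2, comparisons that share no library (Pearson r = 0.49, Spearman rho 0.38). For the same contrasts built from wild-type libraries, r was at most 0.07 in size. Unequal filling progress between the seed samples would predict the r of 0.49. So would wild-type RNA in mutant libraries 2 and 3, or an uneven share of starchy endosperm. The correlation thus cannot tell these causes apart, and genes are not independent replicates. Wild-type RNA mixed into mutant libraries 2 and 3 would move every gene by 1 share, 17.5% and 53.5% from the storage list; of 186 genes at most an eighth of wild type in library 1, 44.6% and 50% lay under 0.5 of that share, which argues against mixing as the whole cause, although the 301 genes of mutant library 3 beyond the range of library 1 and wild type lay within the 94 to 670 of the wild-type libraries, and the 7 of 12 folding genes above that range in it (1236 of 14101 genes, 8.8%, in all) decide nothing, as that list was taken up after BiP1 was seen. A lower share of starchy endosperm would raise markers of the other seed tissues alike. The embryo and aleurone median (-3.14, quartiles -3.37 to -1.64) instead lay below that of green pericarp (0.04, quartiles -0.18 to 0.39). The difference was -3.18 (two-sided permutation p = 0.00074 over genes, which are not independent), -2.37 without mutant library 1 and -4.5 without mutant library 3. These values argue against that share as the whole cause of the falls in that list, largely oleosin, dehydrin and late embryogenesis genes. OSH1, also of that list, did not fall (log2 fold change 0.12). Still open are a part played by that share, since pericarp medians were 0.50, -0.05 and -0.39 in mutant libraries 1, 2 and 3 where storage medians were lowest in library 1, a change within embryo or aleurone, and, untested, seeds sampled younger or filling more slowly at the same age.

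The balance of higher and lower calls changed with the scaling. A few storage genes that take a large share of wild-type counts are a candidate explanation, since total-count scaling then raises all other genes in the mutant. With 25 of them removed, total-count scaling still gave 82.2% higher calls, against 95% before and 50.6% with TMM, which argues against these 25 genes as the whole cause. They account for part of it, as removal lowered the median log2 fold change from 1.27 to 0.54 and the calls from 17344 to 10185. Only 3813 features have a description, so other storage genes may remain in the counts. A broader shift of many abundant transcripts stays open and was not tested.

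For the 32 genes that moved at least 8-fold to a like level in each mutant library, a single introgressed segment is a candidate explanation. They lay on 11 chromosomes, and the fullest window of 50 tested genes held 2 of them (6.2%, one-sided permutation p = 0.89), which argues against 1 segment holding most of them. Regulation by the line difference from elsewhere in the genome stays open and was not tested.

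The real split of the 6 libraries gave 7148 changed genes and 4321 at least 2-fold, and the highest of the other 9 splits gave 0 by edgeR for each (65 to 768 genes at an unadjusted p under 0.05; no other tool was run on the splits). Thus 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. Each of the other 9 splits puts libraries of both lines in each group, so the line difference widens the spread within groups. Few calls there followed from that design, and the 0 is no measure of chance. For gene lists the real split gave 9 calls and the highest other split 13, with 7 of 10 splits, the real one included, giving at least 9 camera calls with a preset correlation. The real split thus did not give the most list calls. Each other split still holds more mutant libraries in 1 group than in the other, so part of the line difference remains in it. The number of lists called there is therefore no measure of chance either.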
